A study of Rattus norvegicus with 14 samples.

How the data were processed

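Gene expression was measured in the livers of rats with 1-colour Affymetrix arrays, on which biotin-labelled RNA of 1 sample is hybridised to probe sets, each a group of short probes for 1 transcript. The 14 arrays held liver RNA of Wistar rats and of rats whose strain is called Kyoto in the labels, fed chow with or without 1% orotic acid. The groups were taken from the source labels: 3 Wistar controls, 2 Wistar rats at day 3 of feeding, 3 Wistar rats at day 14, and 2 Kyoto rats each at days 1, 3 and 14. Kyoto controls and Wistar rats at day 1, which the extraction protocol mentions, were not analysed here. The labels do not say that each array was a separate animal in so many words, so p-values of single genes measure the spread between these samples.

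The authors deposited probe set signals, intensity values on a linear scale, made with MAS5, per the submitters' processing notes. The version, the scaling target and any filter are not given in the sources used here, and detection calls were not used here. The table held 4502 rows, 24 of them control probe sets, with values from 0.64 to 47930. On 11 arrays the median deposited signal was the same, 233.1972, so the arrays had been scaled before deposit. The other 3 arrays (Kyoto day 1 replicate 1, Wistar day 14 replicate 3 and Wistar control 3) had no value in 374 or 375 rows. In all, 375 rows lacked a value on at least 1 array and were left out, and 0 of them would have passed the filter on low signals. The number of arrays limits the precision.

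A rule set before the data were examined decided the scaling. The 2% trimmed means ranged from 797 to 1094, a spread of 37.2% against a limit of 5%, so log2 signals were quantile normalized between arrays with limma 3.58.1 in R 4.3.3. Signals under the 25th percentile of all scaled values, 115 (6.85 on the log2 scale), were set to that floor. A gene with several probe sets was represented by the one with the highest mean. This left 3181 features, of which the upper 60% by mean log2 signal, 1909, were tested; 1502 of these carried 1 gene symbol and 407 did not and are not named. Of all probe sets, 3700 had 1 symbol in the platform annotation, 229 had several and 573 had none. Gene IDs of 3688 probe sets matched the reference table, which changed 0 symbols.

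All 14 arrays entered 1 linear model of 6 group means with 8 residual degrees of freedom (limma lmFit and eBayes with an intensity trend). There were 8 comparisons, each with a Benjamini-Hochberg adjusted p threshold of 0.05. The adjusted p-values of single genes below are from this limma fit, values after ± are standard errors of the log2 difference unless called SD, and a fold is 2 raised to that difference. A difference in which arrays of the lower group lie at the floor is only a bound, written as at least. Before the data were examined, 31 gene lists were fixed, and the 24 with at least 5 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01. Each was tested again with a correlation estimated from the residuals and with fry. Counts of members past the threshold were made over all features and adjusted over the list alone. The adjusted p of a list below is from camera with the preset correlation unless stated otherwise. That p compares genes with genes and does not measure the spread of a list mean between arrays.

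Genes were named by a rule also fixed beforehand. It took the 10 largest rises and falls past the threshold with no overlap between groups in Wistar day 14 against control, and the 5 largest in every other comparison. For each list described it took up to 4 members past the threshold, or up to 2 with the smallest p where none passed. A fixed set of genes was always named in Wistar day 14 against control where tested, and those tested were all lipid genes. Where a comparison had no or few genes past the threshold, those with the smallest p were chosen after their values were seen, and list members named beyond these limits were also chosen then.

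The model was tested on simulated data with 200 changed genes among 1909, 50 each at 1.5, 2, 4 and 8-fold. The simulated noise was independent between genes and had no floor. So many large changes also ease the adjusted threshold, so the recovery given here is likely too high for data with few changes. At a 2-fold change it recovered 60% in Wistar day 14 against control, 84% in Kyoto against Wistar and 14% in the strain by time interaction; at 4-fold it recovered 98%, 100% and 80%. The alternatives were other scalings, floors, filters and probe set rules, a block for the lot batch and fits on fewer groups. Other variance settings, array weights and leaving out each array in turn were also tried. The labels give lot batch 1 for 11 arrays and none for 3, all Wistar. The lot batch block therefore sets lot batch 1 against a missing label. Chosen after seeing the data were the signals as the authors scaled them, a block for the 3 arrays with blank rows, leaving out both the array labelled Wistar control 2 and Kyoto day 1 replicate 1, and the gene lists under the settings planned for genes.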

Results

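Orotic acid, an intermediate of pyrimidine synthesis, causes a reversible fatty liver in rats when added to chow. The arrays ask how liver transcripts differ after 3 and 14 days of feeding in Wistar rats, how they differ between days 1, 3 and 14 in Kyoto rats, and how the strains differ. Over the 4127 rows with a value on every array, the median signals ran from 269.5 to 285.7.

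One array stood apart from its label. The array labelled Wistar control 2 correlated most highly with Kyoto day 3 replicate 2 (r = 0.961 across genes, which are not independent replicates). Its Ces2e signal, of a carboxylesterase gene, was at the floor of 6.85 (log2), as on the Kyoto arrays, against a mean of 10.43 on Wistar controls 1 and 3. Its Mst1 signal, of a liver-secreted growth factor gene, was 7.33 against 11.08. Over 79 features that differed between the strains in a fit without any control array, its median position was 0.938 on a scale from the fed Wistar mean at 0 to the fed Kyoto mean at 1, and Wistar controls 1 and 3 lay at 0.0898 and 0.0689. It stays in the control group as labelled, and every direction against control below draws on it. Wistar day 14 replicate 3 and Wistar control 3 were each other's nearest array (r = 0.970). This alone does not mark either as out of place, because other arrays were also nearest to one of another group. Wistar day 3 replicate 1 and Wistar day 14 replicate 1, for example, were each other's nearest (r = 0.968). Wistar day 14 replicate 3 and Wistar control 3 also both have blank rows and no lot batch given. A shared set of arrays therefore cannot be told apart from a likeness of the livers. Wistar day 14 replicate 3 stays in the day 14 group as labelled, and every Wistar day 14 value below draws on it.

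**Figure D1:**
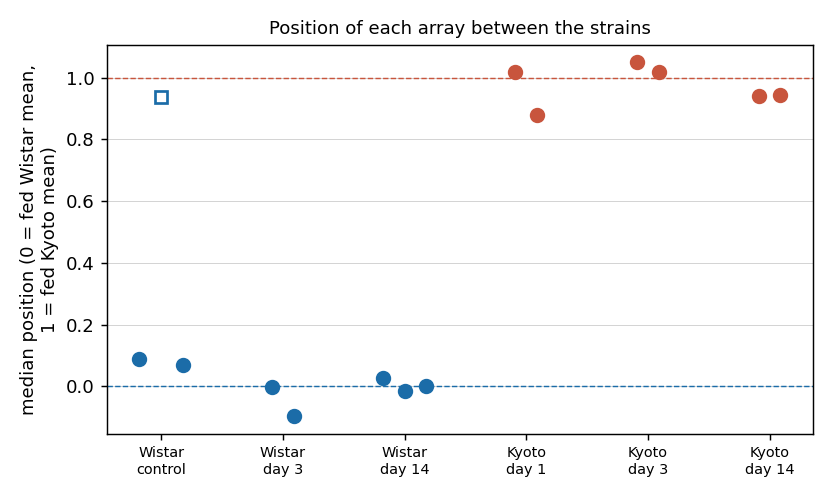
Median position of each array (1 symbol per array, by group) over 79 strain-different features, where 0 is the mean of fed Wistar and 1 the mean of fed Kyoto arrays at days 3 and 14. Those 9 fed arrays define the scale; the open square is the array labelled Wistar control 2, at 0.938, while the other 2 controls lie at 0.0898 and 0.0689.

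After 14 days of orotic acid, the endoplasmic reticulum chaperone and stress genes were higher in Wistar livers as a group. Of 12 measured members, 11 had a higher mean than in controls and 1 a lower one, with a mean difference of 0.49 log2 (adjusted p = 3.35e-05; adjusted p = 0.757 with an estimated correlation). None of the 12 passed over all genes and 1 passed adjusted over the list alone. That member, Pdia4, a protein disulfide isomerase, was 2.5-fold higher (1.32 ± 0.37 log2, 3 against 3 arrays, adjusted p = 0.602 over all genes). Slc3a2, the heavy chain of amino acid transporters, differed by 0.67 ± 0.26 log2. The difference was not on every array: Wistar day 14 replicate 3, at -0.60, lay within the control range of -0.78 to -0.52 on the centred list mean, and without Wistar day 14 replicate 1 the mean was 0.29 and the adjusted p 0.052, and without replicate 3 the mean was 0.73.

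**Figure D2:**
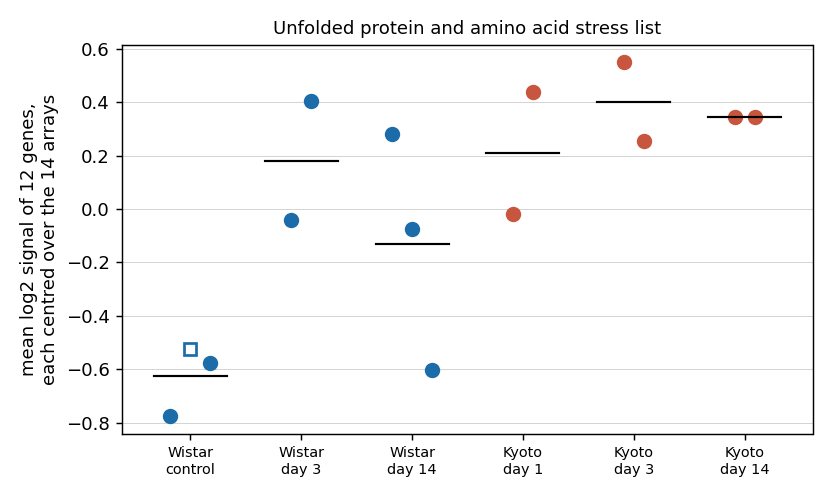
Mean log2 signal of 12 unfolded protein and amino acid stress genes, each centred over the 14 arrays, with 1 symbol per array and a line at each group mean. Wistar controls lie from -0.78 to -0.52; Wistar day 14 replicate 3 lies at -0.60, and the open square is the array labelled Wistar control 2.

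No single gene passed the threshold at day 14: 0 of 1909 features by limma, with 99 at an unadjusted p under 0.05 where chance gives 95, and a smallest adjusted p of 0.408. Among lipid genes, Fasn, the fatty acid synthase, differed by 2.06 ± 0.50 log2 (4.17-fold higher, adjusted p = 0.546) and passed adjusted over its list alone, as did Elovl5, a fatty acid elongase, at -0.64 ± 0.19. The difference was 0.63 ± 0.34 for Srebf1, the lipogenic transcription factor, 0.24 ± 0.48 for Scd, the stearoyl-CoA desaturase (-0.24 without the array labelled Wistar control 2 and -0.08 without Wistar day 14 replicate 2), and -0.59 ± 0.23 for Plin2, a lipid droplet coat protein. It was -0.54 ± 0.28 for Cpt1a, which admits fatty acids to mitochondria, -0.49 ± 0.37 for Apob, the VLDL scaffold, 0.34 ± 0.40 for Cyp7a1, the rate-limiting enzyme of bile acid synthesis, -0.17 ± 0.20 for Pemt and -0.14 ± 0.24 for Fabp1. None of these passed over all genes. With single arrays left out the difference ran from -0.85 to -0.30 for Cpt1a (-0.30 without the array labelled Wistar control 2), 0.37 to 0.80 for Srebf1, 0.15 to 0.72 for Cyp7a1, -0.37 to -0.04 for Pemt and -0.31 to 0.11 for Fabp1. The genes with the smallest p, chosen after their values were seen, were Rps24 (at least 2.09 log2 higher, with 1 control at the floor), Rpl5 (at least 2.36-fold higher, with all controls at the floor) and Gucy1b2 (-0.95 ± 0.22), each with an adjusted p of 0.408. Rps24 and Rpl5 belong to the ribosomal protein list and do not stand for it. The centred mean of its 35 tested genes was 0.001 in Wistar controls, -0.05 at day 3 and -0.02 at day 14. Without Wistar day 14 replicate 3, 7 features passed.

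At day 3 of feeding the same chaperone list was again higher in Wistar rats, by a mean of 0.81 log2 with 11 of 12 members up (adjusted p = 1.92e-06; adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone 5 members passed, and over all genes none did. Hsp90b1, the chaperone of the endoplasmic reticulum lumen, was 4.41-fold higher (2.14 ± 0.46 log2, adjusted p = 0.0959, 2 against 3 arrays) and Pdia4 3.63-fold (1.86 ± 0.41, adjusted p = 0.0959). Hspa5, which encodes the chaperone BiP, differed by 1.16 ± 0.44 and Dnajb9, its co-chaperone, by 1.17 ± 0.42, both chosen after their values were seen. The day 3 and day 14 comparisons share their controls, so their agreement is not independent.

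Genes of fatty acid synthesis went both ways at day 3, and their list did not pass (adjusted p = 0.982). Adjusted over the list alone 2 passed upwards and 2 downwards. Gpam, which starts triglyceride synthesis, differed by 2.06 ± 0.47 log2 (adjusted p = 0.0996) and Fasn by 1.59 ± 0.56, whereas Scd differed by -1.96 ± 0.53 and Elovl5 by -0.57 ± 0.21. Without Wistar day 3 replicate 2 the Scd difference was -1.09, and without Wistar day 3 replicate 1 it was -2.83. Fasn and Elovl5 were chosen here after their values were seen. Eci1 and Hadhb, of mitochondrial fatty acid oxidation, differed by 0.77 ± 0.23 and 0.63 ± 0.21, and Plin2 by -0.87 ± 0.26. Over all features limma called 0, with 200 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0669, that of Rpl5, at least 3.51-fold higher as all controls lay at the floor, chosen after its value was seen. With array weights the count was 18, and with only the 2 groups in the fit 5.

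Between days 3 and 14 in Wistar rats no list and no gene passed (0 of 1909 by limma, 85 at an unadjusted p under 0.05, smallest adjusted p 0.994). Scd, chosen after its value was seen, had a mean log2 signal of 9.72 ± 1.23 (SD, n = 2) at day 3 and 11.91 ± 0.63 (SD, n = 3) at day 14. It passed adjusted over the fatty acid synthesis list alone (2.19 ± 0.53). Without Wistar day 3 replicate 2 the Scd difference was 1.33, and without Wistar day 3 replicate 1 it was 3.06. Cpt1a, chosen in the same way, differed by -1.06 ± 0.32. Leaving out 1 array at a time gave 0 to 4 lists.

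In Kyoto rats from day 1 to day 3 of feeding, 4 lists passed. Stellate cell and fibroblast markers fell as a group (mean -0.44 log2, 8 of 9 members lower, adjusted p = 0.0214; adjusted p = 0.573 with an estimated correlation). Among them Col1a1, a collagen chain, differed by -1.57 ± 0.60 and Sparc, a matrix glycoprotein, by -0.97 ± 0.29. The Col1a1 difference was -0.966 without Kyoto day 3 replicate 2 and -2.18 without Kyoto day 3 replicate 1. Oxidative phosphorylation rose (mean 0.24, 20 of 24 higher, adjusted p = 0.0228; adjusted p = 0.725 with an estimated correlation), with Atp5f1e and Atp5po, subunits of ATP synthase, at 0.74 ± 0.25 and 0.72 ± 0.24. Fatty acid synthesis and glycolysis with gluconeogenesis fell (means -0.46 and -0.27, both adjusted p = 0.0287; adjusted p = 0.573 and 0.725 with an estimated correlation), with Gpam at -1.79 ± 0.51 and Pc, the pyruvate carboxylase, at -0.92 ± 0.30. No feature passed by limma (112 at an unadjusted p under 0.05). Kyoto day 1 replicate 1 had the lowest median correlation with the other arrays (0.895); without it 2 lists passed, and none of the 4 was among them: the mean of stellate cell markers was -0.43, that of oxidative phosphorylation 0.10, of glycolysis -0.10 and of fatty acid synthesis -0.33. Without Kyoto day 3 replicate 1 the mean was -0.465 for stellate cell markers, 0.115 for oxidative phosphorylation and -0.267 for fatty acid synthesis, and Atp5f1e differed by 0.434. Without Kyoto day 3 replicate 2 the mean was -0.084 for glycolysis, and Atp5f1e differed by 1.05. Without Kyoto day 1 replicate 2, which leaves Kyoto day 1 replicate 1 alone in its group, the mean was -0.455 for stellate cell markers and -0.588 for fatty acid synthesis.

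From day 1 to day 14 in Kyoto rats Cyp2a1, a testosterone-hydroxylating cytochrome P450, rose 3.58-fold (1.84 ± 0.25 log2, 2 against 2 arrays, adjusted p = 0.00874). It was the only feature called, with 194 at an unadjusted p under 0.05. With single arrays left out, each fit leaving 1 array in a group, the Cyp2a1 difference ran from 1.72 to 1.96 log2. That range bears on the size of the difference and not on whether it passes. With only the groups compared in the fit, and with array weights, 0 features passed. The cholesterol synthesis list fell (mean -0.64 log2, 12 of 14 lower, 4 of them past adjusted over the list alone, adjusted p = 0.000246; adjusted p = 0.332 with an estimated correlation). Sqle, the squalene epoxidase, differed by -2.05 ± 0.45 and Msmo1, a sterol methyl oxidase, by -1.71 ± 0.37. Microsomal cytochromes P450 rose (mean 0.52, 19 of 26 higher, adjusted p = 0.000399; adjusted p = 0.303 with an estimated correlation), but without Kyoto day 1 replicate 1 the mean was 0.23 and the adjusted p 0.232.

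Amino acid metabolism genes also rose from day 1 to day 14 in Kyoto (mean 0.31, 23 of 35 higher, adjusted p = 0.000941; adjusted p = 0.303 with an estimated correlation). Ddc, the aromatic amino acid decarboxylase, differed by 1.24 ± 0.27 and Tdo2, which opens the tryptophan ring, by 1.04 ± 0.24, while Glul, the glutamine synthetase, chosen after its value was seen, differed by -1.78 ± 0.44. The mean of the amino acid list was 0.246 without Kyoto day 1 replicate 2 and 0.212 without Kyoto day 14 replicate 1. Stellate cell markers fell (mean -0.60, 9 of 9 lower, adjusted p = 0.00131, and adjusted p = 0.303 with an estimated correlation), with Igfbp3 at -1.07 ± 0.32 and Bgn at -0.92 ± 0.28. Cell cycle genes fell too (mean -0.55, 7 of 7 lower, adjusted p = 0.0197, and adjusted p = 0.303 with an estimated correlation). The cell cycle mean was -0.47 without Kyoto day 1 replicate 2 and -0.424 without Kyoto day 14 replicate 1. Peroxisomal fatty acid oxidation (mean 0.47, adjusted p = 0.00878), oxidative phosphorylation (0.28, adjusted p = 0.00708) and conjugation enzymes (0.34, adjusted p = 0.0158) passed upwards, with adjusted p = 0.374, 0.389 and 0.454 with an estimated correlation. Without Kyoto day 1 replicate 1 their means were 0.14, 0.14 and 0.02 and their adjusted p 0.714, 0.232 and 0.888, and 5 lists passed in all. Oxidative phosphorylation also had an adjusted p of 0.0556 (mean 0.23) without Kyoto day 14 replicate 1.

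From day 3 to day 14 in Kyoto rats, cholesterol synthesis genes fell as a group (mean -0.64 log2), with 13 of 14 members lower (adjusted p = 2.47e-05; adjusted p = 0.381 with an estimated correlation). Sqle differed by -2.08 ± 0.45 (mean log2 signal 9.20 ± 0.60 at day 3 and 7.12 ± 0.24 at day 14, SD, n = 2 each) and Msmo1 by -1.21 ± 0.37; both passed adjusted over the list alone and neither over all genes. Cell cycle genes fell with 7 of 7 members lower (mean -0.78, adjusted p = 0.000398; adjusted p = 0.084 with an estimated correlation), among them Ccnd1, cyclin D1, at -1.20 ± 0.44. Fatty acid synthesis genes rose (mean 0.69, 6 of 8 higher, adjusted p = 0.00735, and adjusted p = 0.366 with an estimated correlation), led by Scd at 2.09 ± 0.58 and Gpam at 1.30 ± 0.51. Without Kyoto day 3 replicate 1 the list mean was 0.5, with Gpam at 0.717 and Scd at 2.46.

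Amino acid metabolism (mean 0.20, adjusted p = 0.00233), cytochromes P450 (0.32, adjusted p = 0.00735), conjugation enzymes (0.22, adjusted p = 0.00876), peroxisomal fatty acid oxidation (0.32, adjusted p = 0.0158) and growth hormone dependent and sex-dimorphic genes (0.20, adjusted p = 0.0278) also rose between these days. With an estimated correlation their adjusted p were 0.381, 0.447, 0.472, 0.472 and 0.487. Of these only cytochromes P450 passed without each array in turn. Without Kyoto day 3 replicate 1 the adjusted p was 0.0937 for conjugation and 0.118 for peroxisomal oxidation, at means of 0.22 and 0.32, and 0.359 for the growth hormone list (mean 0.16), and without Kyoto day 14 replicate 1 it was 0.0535 for both conjugation and peroxisomal oxidation (means 0.20 and 0.30). Amino acid metabolism had a mean of 0.08 (adjusted p = 0.229) without Kyoto day 3 replicate 2 and 0.11 (adjusted p = 0.17) without Kyoto day 14 replicate 1; the growth hormone list had a mean of 0.12 (adjusted p = 0.174) without Kyoto day 14 replicate 2 and of 0.06 (adjusted p = 0.216) with the upper 40% of features only. Cyp2c12, a steroid hydroxylase higher in female rat liver, differed by 1.43 ± 0.51. No single feature passed by limma (0 of 1909, 88 at an unadjusted p under 0.05, smallest adjusted p 0.319).

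**Figure D3:**
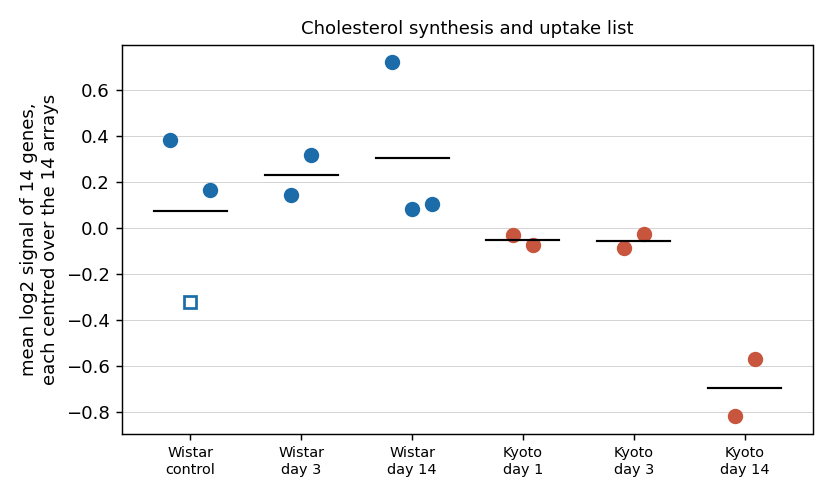
Mean log2 signal of 14 cholesterol synthesis and uptake genes, each centred over the 14 arrays, with 1 symbol per array and a line at each group mean. The Kyoto day 14 arrays lie at -0.82 and -0.57, below every other array, and the open square is the array labelled Wistar control 2, at -0.32.

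Fed Kyoto and fed Wistar rats differed in 62 features, 24 higher and 38 lower in Kyoto, in the mean of the day 3 and day 14 differences (4 Kyoto against 5 Wistar arrays). Of the 62, 15 carry no gene symbol and are not ranked here. The strain differences given here and below are of probe set signal, and whether the probes bind the transcripts of both strains alike was not tested. Among those with one, lowest in Kyoto were Ces2e, at the floor on all 4 arrays and at least 12.5-fold lower (adjusted p = 0.00556), and Mst1, at the floor on 1 of the 4 and at least 10.2-fold lower (adjusted p = 0.00819). Agxt2, a mitochondrial aminotransferase, was 4.46-fold lower, Fmo1, a flavin monooxygenase, 4.3-fold and Aldh1a1, a retinaldehyde dehydrogenase, 4.28-fold. Highest in Kyoto was Akr1c13, an aldo-keto reductase, 5.98-fold higher (2.58 ± 0.34, adjusted p = 0.00236). Cdh17, a cadherin, was at the floor on all fed Wistar arrays and at least 3.17-fold higher, Cela1, an elastase, 3.12-fold, Nupr1, a stress-induced nuclear protein, 2.9-fold and Mx2, an interferon-induced GTPase, at the floor on 2 fed Wistar arrays, at least 2.87-fold.

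**Figure D4:**
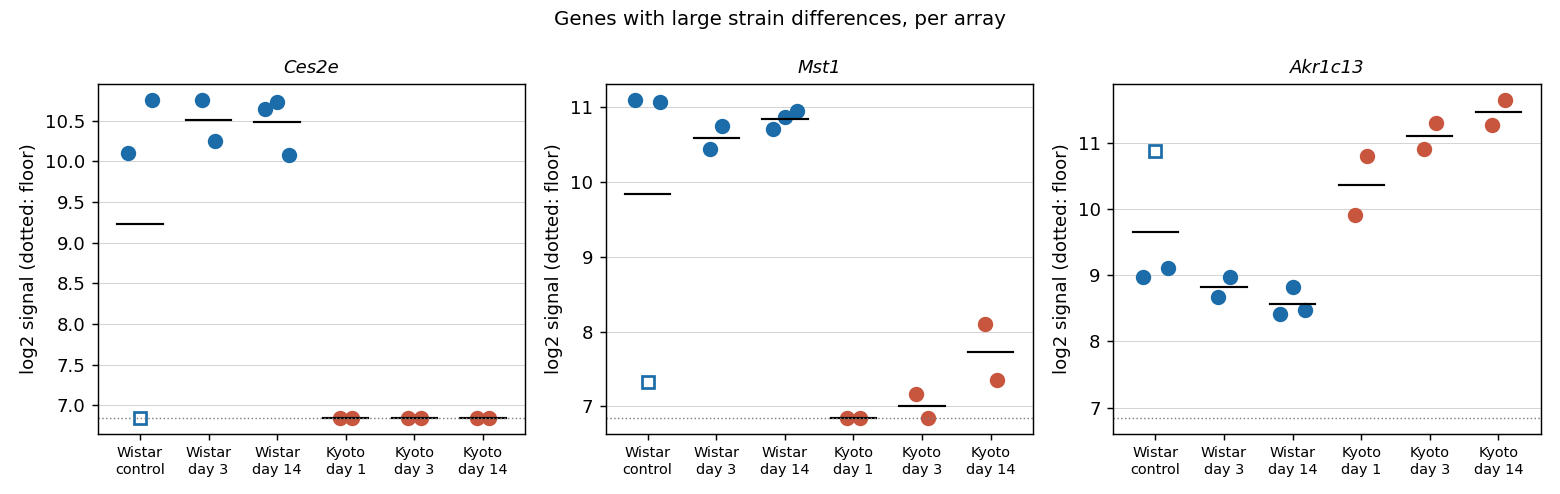
Log2 signal of Ces2e, Mst1 and Akr1c13 on each array, with 1 symbol per array, a line at each group mean and the floor of 6.85 dotted. The open square is the array labelled Wistar control 2, which lies with the Kyoto arrays for all 3 genes.

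As groups, cholesterol synthesis genes were lower in fed Kyoto rats in the mean of both days (-0.64 log2, 11 of 14 lower, adjusted p = 4.60e-06, and adjusted p = 0.569 with an estimated correlation). The gap was wider at day 14: the centred list mean was -0.06 in Kyoto and 0.23 in Wistar at day 3, and -0.69 and 0.30 at day 14. The same Kyoto day 14 arrays enter the day 3 to day 14 and interaction results of this list, so these results are not independent. Over all genes 4 members passed and adjusted over the list alone 7 did. The 4 were Idi1 (-1.94 ± 0.40), Acat2 (-1.39 ± 0.29), Msmo1 (-1.25 ± 0.25) and Cyp51 (-1.18 ± 0.23), enzymes along the route from acetyl-CoA to cholesterol. Macrophage and antigen presenting cell markers were higher (mean 0.41, 12 of 14 higher, adjusted p = 0.00146; adjusted p = 0.569 with an estimated correlation), 3 past over all genes and 5 adjusted over the list alone. RT1-DMb, of the class II peptide loading complex, was 1.96-fold higher, Ctss, cathepsin S, 1.79-fold and Clec4f, a Kupffer cell lectin, 1.76-fold. With no Kyoto controls analysed here, baseline and response cannot be separated. Leaving out 1 array at a time gave 12 to 58 features (12 without Kyoto day 14 replicate 1 and 16 without Wistar day 3 replicate 2), a block for the lot batch gave 20, and leaving out the array labelled Wistar control 2 and Kyoto day 1 replicate 1, neither of which enters the contrast, gave 119.

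The strain by time interaction asks whether the change from day 3 to day 14 differs between strains. By limma 0 of 1909 features passed, with 99 at an unadjusted p under 0.05 and a smallest adjusted p of 0.377, that of Rpl5 (at least 2.30 log2, with 1 Kyoto day 3 array at the floor), chosen after its value was seen. By camera 6 lists passed. The cholesterol synthesis list had a mean interaction of -0.71 log2, a lower Kyoto than Wistar change, negative in 13 of 14 members (adjusted p = 0.00132; adjusted p = 0.518 with an estimated correlation), with Sqle at -2.08 ± 0.61 and Msmo1 at -1.39 ± 0.50. Mitochondrial fatty acid oxidation differed by 0.40, towards higher in Kyoto (adjusted p = 0.00703; adjusted p = 0.392 with an estimated correlation), with Cpt1a at 1.44 ± 0.47 and Hadhb at 0.83 ± 0.31. Without Wistar day 3 replicate 1 no list passed, and without Wistar day 14 replicate 2, 2 did. The simulated interaction recovered 14% of 2-fold changes, so an absence of calls here says little.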

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

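The tests of the strain of the array labelled Wistar control 2, of its part in the chaperone difference, of the spread between single arrays and of the GAPDH ratio were chosen after the result was seen.

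The change from day 3 to day 14 differed between strains in 6 lists by the test of the interaction itself. Its mean was -0.71 log2 for cholesterol synthesis and uptake, 0.40 for mitochondrial fatty acid oxidation and ketogenesis, 0.45 for peroxisomal and microsomal fatty acid oxidation, 0.27 for amino acid metabolism and urea cycle, -0.69 for cell cycle and replication and 0.29 for growth hormone dependent and sex-dimorphic genes. With an estimated correlation the adjusted p were 0.518, 0.392, 0.538, 0.518, 0.392 and 0.638, so none of the 6 held there. With the preset correlation and other settings, cholesterol passed in 21 of 22 and mitochondrial oxidation in 20 of 22, but peroxisomal oxidation in 16 of 22, amino acid metabolism in 17 of 22, cell cycle in 14 of 21 and the growth hormone list in 13 of 22. With the signals as the authors scaled them the means were 0.23 for mitochondrial oxidation, 0.24 for peroxisomal oxidation, 0.03 for amino acid metabolism and 0.07 for the growth hormone list; without Kyoto day 3 replicate 2 the amino acid mean was 0.15, and without Wistar day 14 replicate 1 the growth hormone mean was 0.18.

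The cholesterol list was weighed further. With 1 of the 9 arrays of those days left out, the mean interaction kept at least 0.706 of its value, so a single array did not account for its size, although without Wistar day 3 replicate 1 the adjusted p was 0.0557. The beta-actin 3' to 5' signal ratio of the Kyoto day 14 arrays, 1.32 and 1.34, lay within the range of the other 12 in 2 of 2 arrays. That range is wide, from 1.06 to 1.97, and no such ratio was tried as a term for the interaction. RNA integrity is therefore not decided here. A strain difference in the response to feeding stays open as a hypothesis, as does a shared deviation of the 2 Kyoto day 14 livers, which share a group and cannot be separated from it.

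The array labelled Wistar control 2 lay with the Kyoto arrays. Its median position between the strains was 1.01 over features higher in Kyoto and 0.873 over features lower in Kyoto, consistent with liver RNA of a Kyoto rat under a Wistar label. Dim hybridization is argued against by Wistar day 14 replicate 3, whose spike-in signal was as high (11.86 against 11.63 log2) and whose position, held out of the definition, was 0.121. Mixed RNA of both strains, with Wistar a large part, is argued against by Ces2e, the only feature at the floor on all fed Kyoto arrays and bright in fed Wistar (3.65 log2 above the floor), which lay 0 log2 above it; 4 features near the floor, a set widened afterwards, gave 0.04. A rule that left this test undecided under 3 features was added after its value was seen and then dropped for the bound written beforehand, and a small share of Wistar RNA is not excluded.

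The chaperone list was higher in fed Wistar rats with the preset correlation, but not with an estimated one (adjusted p = 0.757 at day 14 and 0.628 at day 3). Without the array labelled Wistar control 2 the day 14 difference was 1.1 times its value, so the strain of that array does not account for it. Under trimmed mean scaling the difference relative to the median feature was 0.917 times its main value. A single factor per array cancels in that value, the floor aside. It therefore shows only that the difference does not hang on quantile normalization, and it cannot test other factors per array. RNA integrity is argued against as the whole cause only through a linear slope within groups. The GAPDH 3' to 5' ratio was 1.79 to 3.38 in controls and 1.16 to 1.35 at day 3, with no overlap. With it as a term the day 3 difference was 1.00 ± 0.35 log2 (SE), 1.24 times the 0.81 ± 0.27 without it. The slope on the log2 ratio was 0.23 ± 0.27 (SE), not told apart from 0, so a part played by RNA integrity stays open. The part of the sets of arrays stays open, in a reading of the spread chosen after the values were seen: within the 11 arrays without blank rows the difference was 0.75 ± 0.22 log2 (SE), 1.52 times the value on all arrays, whereas between day 14 replicate 3 and control 3, which have blank rows, it was -0.02, the change of sign set down beforehand as speaking for the sets, near 0 but a distance of -0.78 ± 0.38 (SD) from the other arrays. With 1 such array per group, the sets, a weaker response of that animal and a control under a day 14 label cannot be told apart.

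In Wistar day 14 against control the real grouping gave 0 features and the highest of the other splits gave 0; 10 of 10 splits gave as many, as they must with a real count of 0, so this decides nothing. In Kyoto against Wistar the real grouping gave 62 features, and 1 of 60 splits within each day gave as many, namely the real one. The highest of the others was 12, with Wistar day 3 replicates 1 and 2 and Wistar day 14 replicates 1 and 2 on 1 side. That split is the strain grouping apart from Wistar day 14 replicate 3, so its count carries the strain difference. All remaining splits gave 0. Splits that mix the strains within a group carry the strain difference in their spread, which lowers their counts. The real grouping thus stood above the other splits, but with 60 splits chance is not excluded.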

How the results depend on the processing

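Chosen after seeing the data were the authors' scaling, the block for the 3 arrays with blank rows, leaving out both arrays in doubt (labelled Wistar control 2, and Kyoto day 1 replicate 1), and the lists under settings planned for genes. No paired analysis was possible because the numbers in the labels differ for every sample and none is shared between groups. Feature counts stayed within 1.5 times in 90 results and moved in 25, list counts in 91 and 32, leaving out single arrays aside. A count of 0 in both settings was taken as unchanged, and most of the 90 were of this kind. In Kyoto against Wistar, the only comparison with more than 1 feature called, the count ran from 1 to 135. The cause was not tested unless given.

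Wistar day 14 against control gave 3 features and 3 lists with lot batch 1 only, 1 feature and 2 lists with array weights, and 1 feature without both arrays in doubt. Wistar day 3 against control gave 1 feature under trimmed mean scaling, with every probe set on its own, with lot batch 1 only and without both arrays in doubt, 4 with the mean of a gene's probe sets, 5 with only the groups compared and 18 with array weights; trimmed mean scaling gave 2 lists. Wistar day 14 against day 3 gave 2 lists under trimmed mean scaling, the authors' scaling, the 40th percentile floor, no filter and array weights, 3 under the 10th percentile floor and the mean of probe sets, and 4 with lot batch 1 only.

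Kyoto day 3 against day 1 gave 2 features and 2 lists with no filter, 1 feature and 2 lists without both arrays in doubt, and 0 lists with the upper 40% of features, the mean of probe sets and the block for blank rows. Kyoto day 14 against day 1 gave 3 features with no filter, 4 with every probe set, 2 with the mean of probe sets, and 0 with only the groups compared and with array weights; 5 lists passed without both arrays in doubt. Kyoto day 14 against day 3 gave 1 feature with no filter and with array weights, and 5 lists under trimmed mean scaling.

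Kyoto against Wistar gave 1 feature with no filter, 40 with the upper 40%, 20 with the lot batch block, 103 with only the groups compared, 135 with array weights and 119 without both arrays in doubt. With no filter, 294 features at the floor had no spread within groups and the prior degrees of freedom of limma went from 5.78 to 0.873. With an estimated correlation and with fry, 0 lists passed in all 8 comparisons; the mixed test of fry, which asks for change in either direction, called 4 at Wistar day 3 against control, 1 and 9 at Kyoto days 3 and 14 against day 1, and 11 between strains.

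Leaving out 1 array at a time, where a group of 2 keeps 1 array assumed to vary like the other groups, gave 0 to 7 features in Wistar day 14 against control, 0 to 74 in Kyoto day 3 against day 1, 0 to 160 in Kyoto day 14 against day 1 and 12 to 58 in Kyoto against Wistar; the 74 and 160 came without Kyoto day 1 replicate 2 and the 12 without Kyoto day 14 replicate 1. List counts ran from 0 to 4 in Wistar day 14 against control and against day 3, 1 to 6, 5 to 8 and 6 to 8 in the Kyoto times in the order above, 2 to 5 between strains and 0 to 8 in the interaction. Scd at Wistar day 14 against control turned to -0.24 without the array labelled Wistar control 2, also with both arrays in doubt left out; singly left-out arrays gave -0.24 to 0.57. Fabp1 gave -0.31 to 0.11, the latter without Wistar day 14 replicate 1.

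The chaperone list at Wistar day 3 passed in 19 of 19 settings with the preset correlation and at day 14 in 19 of 20; the cholesterol list passed in 22 of 22 between strains and 17 of 17 from day 3 to day 14 in Kyoto, and macrophage markers between strains in 22 of 22. With an estimated correlation none of these held (adjusted p = 0.628, 0.757, 0.569, 0.381 and 0.569 in that order). Signals near the floor limit the size of changes that can be seen.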

Other observations

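The permutation tests, the contrast of both fed times together, the correlation of changes and the genes of the first paragraph were chosen after the data were seen.

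Genes whose liver level depends on sex and growth hormone differed between the strains in both directions, though their list did not pass (adjusted p = 0.0632). Cyp2a2 and Car3, higher in male rat liver, were lower in fed Kyoto rats by limma (-1.53 ± 0.29 and -1.10 ± 0.23 log2, adjusted p = 0.0127 and 0.0171). Cyp3a18, also male-biased, had a difference of -1.69 ± 0.51 (adjusted p = 0.0895), and the female-biased Cyp2c12, at the floor on 3 fed Wistar arrays, had at least 1.26 (adjusted p = 0.0626). Cyp2a1, higher in female rat liver, went the other way (-0.56 ± 0.17, adjusted p = 0.0991), so the direction did not follow sex bias throughout. Oat, the ornithine aminotransferase, was lower (-0.83 ± 0.21, adjusted p = 0.0418) and Igfals, which binds circulating IGF, higher (0.90 ± 0.20, adjusted p = 0.0248). Akr1d1 and Ghr, past adjusted over the list alone, had -0.81 ± 0.22 and 0.96 ± 0.32. The sex of the rats is not given in the sources used here, so no explanation was tested.

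The chaperone list mean of each of the 6 fed Kyoto arrays, from -0.02 to 0.55 log2 (centred), lay above all 3 arrays labelled Wistar control, including the one that lay with Kyoto in its strain genes, at -0.52. Of the 5 fed Wistar arrays 4 lay above all 3 controls. The hypothesis that orotic acid raises this list in Wistar rats at days 3 and 14 together was put to an exact two-sided permutation test of the array means. The difference was 0.62 log2, with an exact p = 0.0893 over 56 splits, where the smallest possible is 0.0179, so the hypothesis was not borne out at 0.05 and stays open. Without the array labelled Wistar control 2 the exact p was 0.143, where the smallest possible is 0.0476. For day 14 alone, 3 arrays against 3 controls, the difference was 0.49 log2 and the exact p 0.3. The smallest possible there is 0.1, so that test could not reach 0.05.

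A limma contrast of both fed Wistar times together against control, tried after the planned comparisons, gave 4 features higher and 1 lower, with a smallest adjusted p of 0.0444. The named ones were Rpl5 (at least 1.53 log2, with all controls at the floor), Rps24 (at least 2.17, with 1 control at the floor) and Gucy1b2 (-1.04 ± 0.20). Without the array labelled Wistar control 2 the count was 0, with a smallest adjusted p of 0.083, while the differences were at least 1.53 for Rpl5, at least 2.33 for Rps24 and -0.95 for Gucy1b2. The calls ended with 2 controls and larger standard errors (0.30, 0.45 and 0.23 in that order, against 0.25, 0.39 and 0.20), at differences of similar size.

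Across 1909 genes, which are not independent replicates, the changes from day 3 to day 14 in Wistar and in Kyoto, from separate arrays, had a Pearson r of -0.0972 and a Spearman rho of -0.127, with a covariance of -0.01.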
